A study of Mus musculus with 18 samples.

How the data were processed

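CGR8 mouse embryonic stem cells with a control hairpin or a hairpin against HEB were profiled in 3 culture states by 3SEQ, with 3 libraries in each of the 6 groups. Per the labels, libraries were made with fragments of 200 to 350 bp and 15 PCR cycles, and the replicates are biological triplicates. The harvest day of the embryoid bodies and the number of hairpins are not stated in the labels.

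The authors deposited raw counts per locus for the 18 libraries, with the tools CASAVA 1.8.2, Trimmomatic 0.32, STAR 2.3.0e, Cufflinks 2.2.1, featureCounts of Subread 1.4.5 and DESeq2 1.2.8 named in their notes, on genome build mm9. The authors' deposited tables also give a log2 fold change of shHEB over shControl per culture state, made with DESeq2. The same tables of the authors give a p-value and an adjusted p-value for each test. Their 18 transformed columns per sample were not used. The deposited annotation has 137025 loci, of which 30570 could be given a gene symbol through their Ensembl transcripts and GENCODE release M21. Symbols come from that release, whose build differs, so all positions are those of the deposited mm9 annotation. Named loci held 97.1% of counts. A locus with several protein-coding symbols (1266 loci) keeps all of them, joined by a slash, and stands for a list only if all its genes are in it, a rule set after the annotation was seen and before any result. Where several loci carry 1 symbol, the locus with the highest mean count was kept and 98 were set aside.

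Library totals ran from 6691853 to 8643786 counts, and 3 counts over a group served as the floor for folds against a group without counts. Ratios for groups with 1 to 3 counts have a 95% counting interval. All 18 libraries were fitted together with 6 group means by the quasi-likelihood F test of edgeR 4.0.16 (limma 3.58.1, R 4.3.3), after filterByExpr by group and TMM scaling. This left 12805 loci, 10571 with a symbol, 12 residual degrees of freedom and a common biological coefficient of variation of 0.202. Tests were two-sided, with Benjamini-Hochberg adjustment over all loci and a threshold of 0.05. The 8 comparisons were knockdown in each of the 3 states, activin in control and in shHEB embryoid bodies, differentiation in control cells, and the interactions of knockdown with activin and with differentiation. The mean of the log2 fold changes was not centred, and the change of scaling to median-of-ratios moved the median by at most -0.0726.

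The design, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, apart from those stated as chosen later. The rule named Tcf12, the 8 largest rises and 8 largest falls of 5 comparisons among named loci past the threshold, with a mean of at least 20 counts and no overlap of libraries, and the 6 largest interactions in each direction. For each list it named up to 4 members past the threshold. The 21 lists covered E proteins and Id proteins, pluripotency, post-implantation epiblast, primitive streak and mesendoderm, definitive endoderm, extra-embryonic endoderm, mesoderm and muscle, blood and endothelium, neuroectoderm, trophoblast, the activin and Nodal pathway, BMP targets, PRC2 components, Hox genes, bivalent developmental transcription factors, epithelial and mesenchymal genes, p53 response, interferon response, hypoxia and glycolysis, cholesterol synthesis and control genes. Of their 399 entries 344 had a locus of their own, 29 shared a locus with genes outside the list and were left out, and 14 were matched to no locus through their transcripts (Pou5f1, Ezh2 and Sox1 among them), which does not show that they have none, and are not analysed here. Some genes are in more than 1 list, so lists are not separate findings. Among them are Foxa2, Gsc and Lhx1 (definitive endoderm and primitive streak) and Id1, Id2 and Id3 (BMP targets and E-protein and Id genes). Lists were tested by camera with an inter-gene correlation of 0.01, adjusted over the 21 lists of a comparison, and again with an estimated correlation. Overlaps were tested by Fisher's exact test.

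The fit was tested on simulated data with 200 changed genes per comparison. Of 2-fold changes it recovered 57% for knockdown in ESC and 23% for the interaction with activin, of 4-fold changes 98% and 76%, with 0 in the wrong direction, and 7.43% and 5.61% of calls were false. Simulated libraries varied independently, and for an interaction the knockdown effect in the other state was left out. The false share under the structure of the real libraries, described below, was therefore not measured. Alternatives were median-of-ratios scaling, replicate number as a block, replicate number within a state as a block, no filter, summed loci per gene, only the groups compared, the Wald test of DESeq2 1.42.0, and each library left out in turn. Fits with only replicates 1 and 3, and with another split of the ESC libraries as a term, were added after the data were seen. Called list members were also counted at an unadjusted p under 0.05 and by DESeq2. Whether equal replicate numbers pair libraries was checked by the correlation of deviations from the group mean across loci over 8 CPM, which are not independent replicates. It was above 0.1 for all 3 numbers between control and shHEB embryoid bodies with activin (0.239, 0.521 and 0.101), between shHEB embryoid bodies without and with activin (0.489, 0.461 and 0.175), and between shHEB ESC and shHEB embryoid bodies without (0.309, 0.374 and 0.423) and with activin (0.318, 0.403 and 0.107). No pairing is stated in the labels, so none was assumed.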

Results

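The data were counts of 3′-end sequencing (3SEQ, in which libraries are primed at the poly(A) tail) from CGR8 mouse embryonic stem cells (ESC) carrying a control short hairpin (shControl) or a hairpin against HEB (shHEB). HEB is the product of Tcf12, a basic helix-loop-helix transcription factor of the E-protein family. Cells were profiled as ESC, as embryoid bodies (EB, floating aggregates of differentiating cells) in serum-free medium without activin, and as EB given 100 ng/ml human activin A, a TGF-beta family ligand, on day 2. The labels call the replicates biological triplicates, so the 6 groups held 3 libraries each, 18 in all. Library totals ran from 6691853 to 8643786 counts. Levels are in CPM (counts scaled to a common library total), fold changes are on the log2 scale with their standard error (SE), and positions are on mouse genome build mm9. Intervals and floors cover counting error only, since PCR copies are not independent molecules. Within the shHEB groups replicate 2 stood apart: the chi-square per degree of freedom of library pairs was 36.5 and 16.8 with replicate 2 and 13.8 without it in ESC, 28.8 and 20.6 against 6.17 in EB without activin, and 34.4 and 18.8 against 7.53 in EB with activin. In shControl, replicate 1 stood apart in ESC (24.4 and 14.9 against 11.5) and in EB without activin (16.85 and 13.98 against 8.09). Replicate 2 did so in shControl EB with activin (12.9 and 11.0 against 6.01). The share of genes whose 3 libraries of both groups did not overlap was 13.9% for knockdown in ESC, 28.5% in EB without activin and 30.8% in EB with activin, where chance gives 10%.

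Tcf12 (ENSMUSG00000032228, chromosome 9, 71692059 to 71959626) was read first as a check on the labels. In ESC the shControl libraries held 12, 15 and 25 Tcf12 counts and the shHEB libraries held 0, 1 and 0, a ratio of 52.2 with a 95% counting interval of 8.97 to 2103. Tcf12 fell by 5.25 on the log2 scale in ESC (SE 0.84, adjusted p 0.00678) and by 1.75 in EB without activin (SE 0.42, adjusted p 0.00871). In EB with activin it did not pass the test, with a log2 fold change of -1.23 (SE 0.46, adjusted p 0.0796), but it passed with replicate number as a block, at -1.205 (SE 0.345, adjusted p 0.0187), with the block within culture states, at -1.20 (SE 0.37, adjusted p 0.0347), and without shControl replicate 2, at -1.55. The shHEB level was 1.74% of control in ESC, 29.6% in EB without activin and 42.3% in EB with activin. The difference between these knockdown effects did not pass, with an interaction of 3.51 between ESC and EB without activin (SE 1.06, adjusted p 0.0671) and of 0.52 for activin (SE 0.64, adjusted p 0.784). The first passed with both blocks, at 3.54 in each (SE 0.84 and 0.91, adjusted p 0.0141 and 0.03), and without EB shControl replicate 3, at 3.92, but with 1 count in shHEB ESC its value depends on the prior count. All libraries held few Tcf12 counts, 69 over the 3 shControl and 29 over the 3 shHEB libraries with activin. The ESC call ended without shHEB replicate 3, at -4.83, and the call in EB without activin ended without shControl replicate 3, at -1.32.

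**Figure D1:**
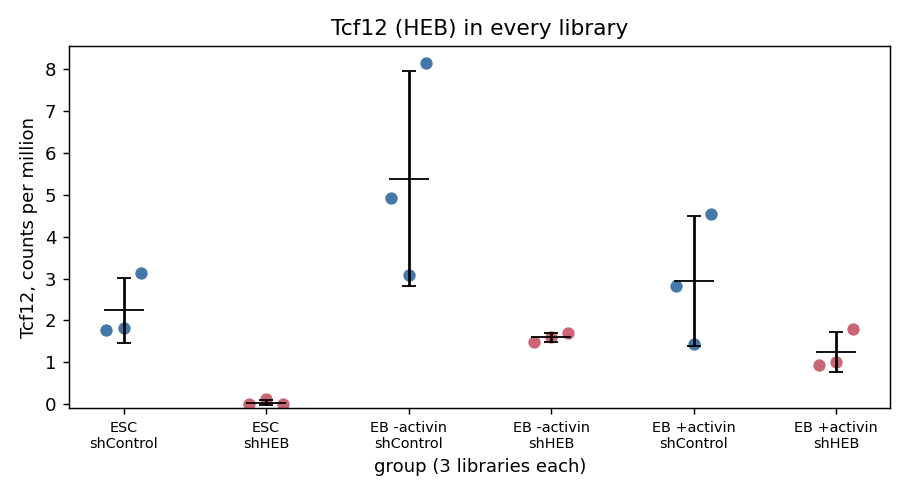
Tcf12 in CPM (vertical axis) in each of the 18 libraries by group, with points for libraries and bars for the mean and SD of 3 libraries. The shHEB ESC libraries lie at or near 0, while those of shHEB EB with activin lie at 29 counts in total against 69 in control.

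**Figure D2:**
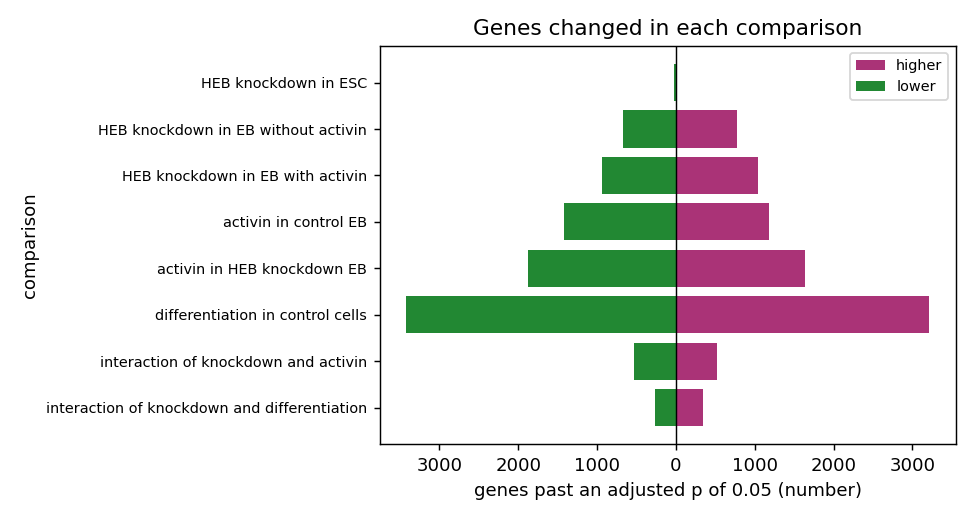
Number of genes past an adjusted p of 0.05 in each of the 8 comparisons, higher to the right and lower to the left of 0. Knockdown changed 35 genes in ESC, 1448 in EB without activin and 1984 in EB with activin.

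The comparison of control EB without activin with control ESC describes differentiation itself. Fezf2, a forebrain transcription factor, was at 178 CPM ± 32.8 (SD, n = 3) in EB and had no count in ESC, at least 1367-fold higher against a floor of 3 counts over the group. The receptor gene Ephb1 was at least 269-fold higher, Zbtb16 at least 50.3-fold, Hesx1 at least 45.1-fold and the retinoic acid hydroxylase gene Cyp26a1 at least 44.5-fold. The Notch effector Hes5 had a ratio of 427 (95% counting interval 76.2 to 16910) and the RNA-binding protein gene Rbm24 a ratio of 292 (99.7 to 1420). Lhx5 rose from 0.592 to 149 CPM. The largest falls were in Slc11a1, from 20.6 to 0.631 CPM, the meiosis gene Stra8 (-4.91), 1700016D06Rik (-4.91), Krt42 (-4.79), Tcl1 (-4.74), Cdx1 (-4.70), Nr0b1 (-4.70) and Chrna9 (-4.68).

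By list, 16 of 17 pluripotency genes fell and 1 did not pass in the change from ESC to EB, the same counts adjusted over the list alone, among them Klf4 (-4.40) and Esrrb (-4.14). Of 13 neuroectoderm genes 8 rose, 4 fell and 1 did not pass, with Neurog2 at least 17.7-fold higher, Otx1 at a ratio of 103 (95% counting interval 18.0 to 4103) and Pax2 at 5.42 (adjusted over the list alone, 8 and 4). Of 10 post-implantation epiblast genes 7 rose, 1 fell and 2 did not pass, with Otx2 at 4.10, Sox3 at 3.99 and the Nodal co-receptor gene Tdgf1 at -3.83 (adjusted over the list alone, 7 and 1). The list tests gave adjusted p 1.17e-14 for pluripotency, 2.25e-06 for neuroectoderm and 0.0105 for epiblast. Under an estimated correlation they gave 0.0164, 0.0029 and 0.0382 in the same order. In total 6637 genes changed, 3214 up and 3423 down. Without ESC shControl replicate 1 or 2, or without EB shControl replicate 3, the rise of Tcf12 itself from ESC to EB (1.26, adjusted p 0.0139) did not pass, at 1.13, 1.10 and 0.86.

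Activin in control EB addresses how these cells respond to the ligand. Genes of the primitive streak and definitive endoderm lists rose and most of the neuroectoderm list fell. Fgf8 rose by 8.54 (SE 0.27), from 2.15 CPM ± 0.648 to 810 CPM ± 77.6 (SD, n = 3 each), the homeobox gene Mixl1 by 8.35 (SE 0.42) and Wnt8a by 6.66 (SE 0.55). The secreted antagonist gene Cer1, with 1 to 3 counts in EB without activin, had a ratio of 3064 (95% counting interval 549.5 to 121100), and the endoderm factor gene Foxa2 a ratio of 162 (55.1 to 787). Lhx1, Upk3a and Alox15 had ratios of 254 (45.2 to 10070), 233 (41.5 to 9251) and 146 (25.7 to 5782). Fezf2 was at least 1393-fold lower with activin, Hes3 at least 178-fold, Lhx2 at least 57.2-fold and Tmem132c at least 43.3-fold. Lhx5 was lower by a ratio of 3502 (628 to 138400), Foxd4 by 186 (51.2 to 1545) and Tlx2 by 140 (38.3 to 1160), and Pax6, a neural and eye transcription factor gene, fell by 6.83 (SE 0.39).

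Of the 14 primitive streak and mesendoderm genes tested, 12 rose with activin in control EB and 2 did not pass, as adjusted over the list alone (list adjusted p 4.2e-53). Of 17 definitive endoderm genes 15 rose and 2 did not pass, with Gsc at 6.51 (adjusted over the list alone, 16; list adjusted p 5.87e-32). Of 13 neuroectoderm genes 9 fell, 1 rose and 3 did not pass, with Neurog2 at least 18.0-fold lower and Hes5 at -6.64 (adjusted over the list alone, 10 fell and 2 rose; list adjusted p 1.19e-13). Of 18 activin and Nodal pathway genes 9 rose, 1 fell and 8 did not pass, the same adjusted over the list alone, among them the target genes Pmepa1 (4.64) and Lefty1/Lefty2 (4.38), with list adjusted p 1.19e-13. Of 17 pluripotency genes 13 fell, 2 rose and 2 did not pass, with Zfp42 at least 8.53-fold and Prdm14 at least 3.23-fold lower and Tcl1 at -4.35 (adjusted over the list alone, 14 and 2). That list had adjusted p 2.97e-07, and adjusted p = 0.084 with an estimated correlation. In all 2598 genes changed, 1175 up and 1423 down.

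Knockdown in ESC compares shHEB with shControl before differentiation. The largest rises were in Acta2 and Myl9, genes of contractile proteins. Acta2 (smooth muscle actin, ENSMUSG00000035783, chromosome 19, 34315580 to 34329993) rose by 3.06 (SE 0.46, adjusted p 0.00479), from 0.799 CPM ± 0.481 to 6.94 CPM ± 0.934 (SD, n = 3 each). Myl9, a myosin light chain gene, rose by 1.88 (SE 0.24) from 65.7 to 241 CPM. The row that joins Sidt2 and Tagln, a smooth muscle marker, rose by 1.24 (SE 0.17). Cnn1, the calponin gene, was looked up after the values of these genes were seen and rose by 0.99 (SE 0.19, adjusted p 0.0311). The Cnn1 call ended whichever ESC library was left out, at 1.03, 0.92 and 1.02 (adjusted p 0.0709, 0.113 and 0.129) without shControl replicates 1, 2 and 3 and at 0.92, 1.05 and 1.00 (0.0762, 0.0612 and 0.139) without shHEB replicates 1, 2 and 3. Of the 14 genes of the mesoderm and muscle list, 1 rose (Acta2) and 13 did not pass (adjusted over the list alone, 1 rose and 1 fell; list adjusted p 0.583). Among the 13 were the muscle genes Des (-0.23), Tnnt2 (0.05), Myl7 (0.12) and Actc1 (-0.25). Of the 14, 3 had an unadjusted p under 0.05 and DESeq2 called 2. Bmp4, a member of this list, stood at -0.966 in the authors' deposited DESeq2 table for ESC (adjusted p 4.86e-05).

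The other large rises with knockdown in ESC were Klhl13 (1.19), the kinesin gene Kif1a (1.15), Apela/Trim60/Trim61 (1.11) and the semaphorin receptor gene Plxnd1 (1.09). The largest falls were Nkx6-3 (-1.46), the transporter gene Slc38a10 (-1.42, SE 0.14, adjusted p 3.73e-05), Arnt, which encodes a basic helix-loop-helix partner protein (-1.07), Ggt1 (-1.05), Snora17 (-1.04), Micall2 (-1.03), Rpsa (-0.98) and Rsrp1/Syf2 (-0.96). Symbols joined by a slash share 1 locus in the deposited annotation, so reads of its genes cannot be told apart. Of 17 pluripotency genes none passed by edgeR, over all genes or adjusted over the list alone, 3 had an unadjusted p under 0.05 and DESeq2 called none. Klf5 was at -0.22 and Utf1 at -0.48 (adjusted p 0.896 and 0.543). The log2 fold change of Klf5 changed sign, to 0.035, without shHEB replicate 1. The list test pointed down at adjusted p 0.0879, and at 0.65 with an estimated correlation. It passed without ESC shControl replicate 1 (0.0222). None of the 10 epiblast genes passed by edgeR over all genes, 4 had an unadjusted p under 0.05, DESeq2 called 1, and 4 were up adjusted over the list alone, with list adjusted p 0.0222 and adjusted p = 0.113 with an estimated correlation. None of the 5 Hox genes passed by edgeR either way, 2 had an unadjusted p under 0.05 and DESeq2 called none, with Hoxb9 at 0.66 and Hoxa7 at 0.67, list adjusted p 0.0222 and adjusted p = 0.113 with an estimated correlation. Without ESC shHEB replicate 2 the adjusted p was 0.0542 for the epiblast and 0.0945 for the Hox list, and without shHEB replicate 3 it was 0.169 and 0.128.

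Of the genes named for knockdown in ESC, 7 beside Tcf12 lost their call without 1 library. Klhl13 (1.19) did so at 1.16, 1.10 and 1.32 without shControl replicates 1, 2 and 3 and at 1.05 without shHEB replicate 3. Kif1a (1.15) did so at 0.99 and 1.10 without shControl replicates 1 and 3 and at 1.00 and 1.12 without shHEB replicates 2 and 3. Apela/Trim60/Trim61 (1.11) did so at 0.99 and 0.98 without shControl replicates 2 and 3 and at 1.05 and 1.01 without shHEB replicates 2 and 3. Plxnd1 (1.09) did so at 0.99 and 1.05 without shControl replicates 1 and 3 and at 1.09 and 0.97 without shHEB replicates 2 and 3. Nkx6-3 (-1.46) did so at -1.33, -1.36 and -1.66 without shControl replicates 1, 2 and 3 and at -1.43, -1.51 and -1.44 without shHEB replicates 1, 2 and 3. Snora17 (-1.04) did so at -0.81, -1.18 and -1.12 and at -0.90, -1.25 and -1.01 in the same order. Rpsa (-0.98) did so at -0.64 and -1.06 without shControl replicates 1 and 3 and at -0.81 and -0.99 without shHEB replicates 2 and 3.

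In all, 35 genes changed with knockdown in ESC, 15 up and 20 down, of 12805 tested. The count was 139 with DESeq2, 113 with replicate number within each culture state as a block, 90 with replicate number as a block, 95 without a filter, and 1 (Slc38a10, named after its value was seen) when only the 6 ESC libraries were fitted. It was 19, 22 and 10 without shControl replicates 1, 2 and 3, and 12 and 11 without shHEB replicates 2 and 3, and 23 with only replicates 1 and 3, a setting chosen after the data were seen. Another split of the ESC libraries, with shControl replicate 1 and shHEB replicates 1 and 3 on 1 side, called 406 genes, and with that split as a term, also chosen after the data were seen, knockdown called 64. Acta2, Myl9, Sidt2/Tagln, Slc38a10, Arnt, Ggt1, Micall2 and Rsrp1/Syf2 were called whichever ESC library was left out.

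**Figure D3:**
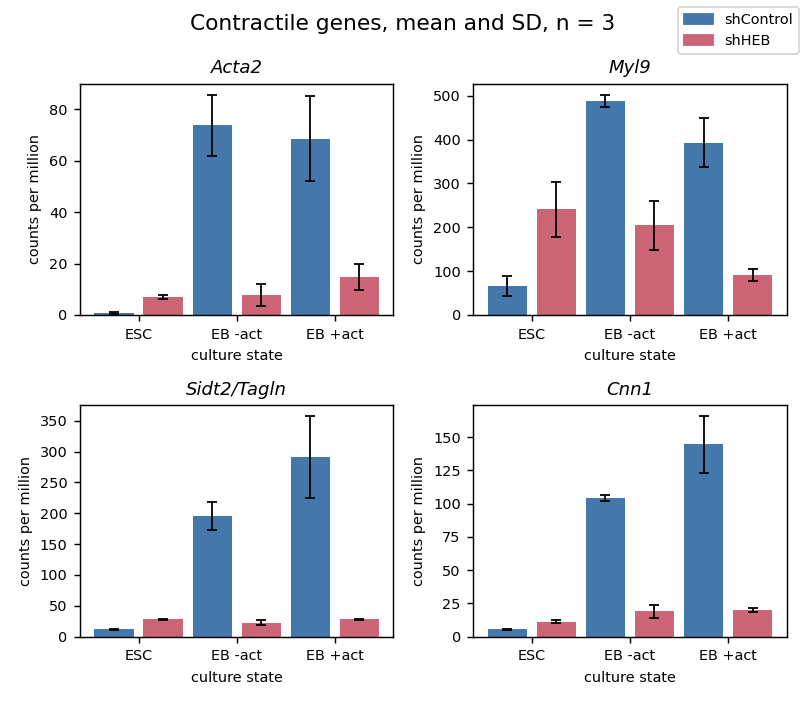
Levels of Acta2, Myl9, Sidt2/Tagln and Cnn1 in CPM (vertical axis, from 0) in the 6 groups, as the mean and SD of 3 libraries. All 4 were higher in shHEB than in shControl ESC and lower in shHEB than in shControl EB, with or without activin.

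Knockdown in EB without activin compares shHEB with shControl during differentiation without the ligand. Genes of the primitive streak list rose. Mesp1, a transcription factor gene of early mesoderm (ENSMUSG00000030544, chromosome 7, 86937127 to 86938674), rose by 9.65 (SE 0.46, adjusted p 5.01e-11), from 0.640 CPM ± 0.439 to 522 CPM ± 237 (SD, n = 3 each). The apelin receptor gene Aplnr rose by 7.62 (SE 0.50), Mixl1 by 7.10 (SE 0.43), Wnt8a by 6.85 (SE 0.55) and Fgf8 by 6.66 (SE 0.26). Cer1, Cdx2 and Lhx1, with 1 to 3 counts in control, had ratios of 246 (95% counting interval 43.8 to 9760), 161 (44.3 to 1337) and 144 (25.5 to 5728). The eye field gene Rax (ENSMUSG00000024518) fell by 7.36 (SE 0.53), from 165 CPM ± 50.8 to 0.991 CPM ± 0.547, and Fezf2 fell by 6.28 (SE 0.35). The anterior gene Six3 (-5.38, SE 0.47) and Pax6 (-3.99, SE 0.30) fell as well.

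The other large falls were Hesx1, lower by a ratio of 68.1 (95% counting interval 18.5 to 568), the small heat shock protein gene Cryab (-5.39), Myoz1/Synpo2l (-4.56) and Foxd4 (-4.17). Of the 14 primitive streak and mesendoderm genes, 13 rose with knockdown in EB without activin and 1 did not pass, as adjusted over the list alone (list adjusted p 1.69e-77). Of 22 bivalent developmental factor genes, which carry repressive H3K27me3 in ESC by textbook knowledge, 13 rose, 4 fell and 5 did not pass, with Evx1 at least 10.7-fold higher (adjusted over the list alone, 14 and 4; list adjusted p 3.59e-15). The list shares 6 genes with the primitive streak list (T, Evx1, Eomes, Lhx1, Gsc and Mixl1), and all 6 are among the 13. Of 17 definitive endoderm genes 7 rose, 4 fell and 6 did not pass, with Foxa2 at a ratio of 41.7 (95% counting interval 13.9 to 205) and Gsc at 3.21 (adjusted over the list alone, 10 and 4, list adjusted p 1.65e-06). Foxa2, Gsc and Lhx1, among the 7, are primitive streak genes as well. Of 18 activin and Nodal pathway genes 5 rose, 1 fell and 12 did not pass, with the activin antagonist gene Fst at 4.05, Nodal at 1.92 and Ltbp1 at -1.33 (adjusted over the list alone, 8 and 1; list adjusted p 0.000191). Of 5 E-protein and Id genes 4 fell and 1 did not pass, as adjusted over the list alone, with Id3 at -1.93, Id1 at -1.83 and Id2 at -1.67 beside Tcf12 (list adjusted p 0.00017). Tcf12 is the target of the hairpin, so its fall enters this count and list test, and the list was not tested without it. The Id2 call ended without shControl replicate 3 (-1.53) and shHEB replicate 3 (-1.47), and that of Tcf12 without shControl replicate 3 (-1.32). Of 8 BMP target genes 4 fell, 1 rose and 3 did not pass, with Bmp4 at -3.31 (adjusted over the list alone, 4 and 2, list adjusted p 0.000393). Beside Bmp4 the falls were Id1, Id2 and Id3, which the E-protein and Id list counts as well. Under an estimated correlation the list adjusted p was 0.0181 for definitive endoderm and 0.0499 for the activin and Nodal pathway. It was 0.0173 for E-protein and Id genes and 0.0366 for BMP targets.

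Among other lists with knockdown in EB without activin, called neuroectoderm, mesoderm and epiblast genes went both ways, while called pluripotency genes only fell. The p53 and cholesterol lists, given under other observations, had calls in a single direction each. Of 13 neuroectoderm genes 4 rose, 3 fell and 6 did not pass, with Hes3 at 4.63, Pax6 at -3.99 and Neurog2 at -3.08 (adjusted over the list alone, 4 and 4; list adjusted p 0.2, and 0.0262 without shHEB replicate 1). Of 14 mesoderm and muscle genes 6 rose, 3 fell and 5 did not pass, with the growth factor receptor gene Kdr at a ratio of 26.7 (95% counting interval 4.42 to 1092), Snai1 at 3.56 and Acta2 at -3.26 (adjusted over the list alone, 6 and 5; list adjusted p 0.809). Of 17 pluripotency genes 2 fell and 15 did not pass, with Utf1 at -1.86 and Sox2 at -1.30 (adjusted over the list alone, 3 fell; list adjusted p 0.019, and adjusted p = 0.358 with an estimated correlation). That list call ended without shControl replicate 1 (0.166) and without shHEB replicates 1 (0.0585) and 2 (0.104). Of 10 epiblast genes 4 rose, 2 fell and 4 did not pass, as adjusted over the list alone, with Fgf15 at 2.73, Lef1 at 2.32 and Otx2 at -1.21 (list adjusted p 0.042, and adjusted p = 0.0953 with an estimated correlation). Its call ended without shControl replicates 2 (0.0554) and 3 (0.0977). In all, 1448 genes changed, 778 up and 670 down, of which 442 and 434 by at least 2-fold.

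**Figure D4:**
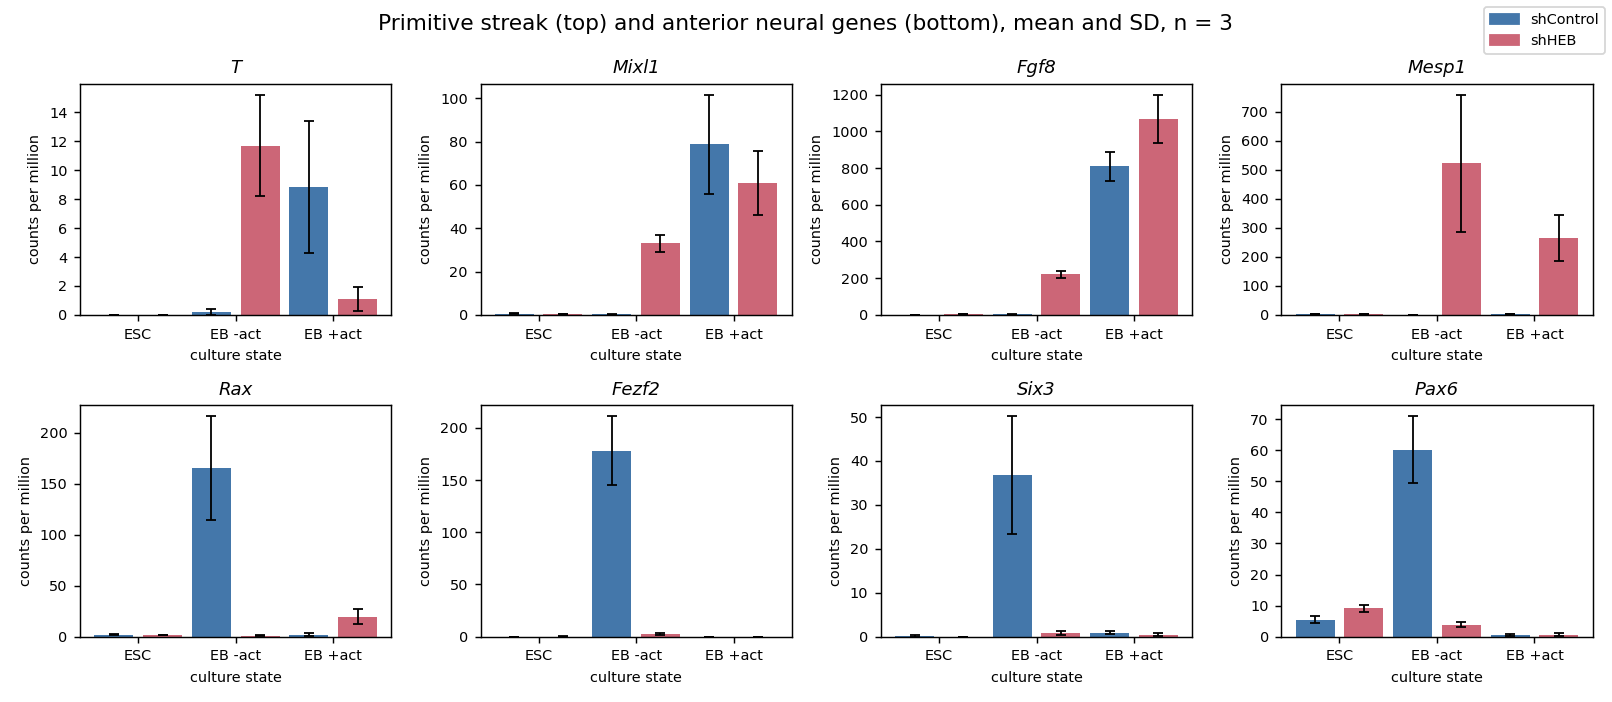
Levels of T, Mixl1, Fgf8 and Mesp1 (top) and of Rax, Fezf2, Six3 and Pax6 (bottom) in CPM (vertical axis, from 0) in the 6 groups, as the mean and SD of 3 libraries. In EB without activin the top genes were higher and the bottom genes lower in shHEB, for Mesp1 at 522 against 0.640 and for Rax at 0.991 against 165.

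Knockdown in EB with activin compares shHEB with shControl in the presence of the ligand, while the interaction below tests the response to it. Tcf12 did not pass here, at 42.3% of control with 1984 genes changed, against 1.74% with 35 genes in ESC. The bikunin precursor gene Ambp had a ratio of 505 (95% counting interval 90.2 to 19970), the heart and limb factor gene Hand2 a ratio of 124 (21.8 to 4923), and Tsga8 a ratio of 98.0 (26.8 to 815). Fgf3 rose by 6.93 (SE 0.55), Mesp1 by 6.52 (SE 0.38), from 2.85 CPM ± 1.36 to 264 CPM ± 79.7 (SD, n = 3 each), Kif12 by 5.86 and Hspbap1/Sema5b by 4.78. The chemokine gene Cxcl10 was lower by a ratio of 55.4 (18.6 to 271), and the falls of Npas4 (-5.24), Alox15 (-4.83), the galectin gene Lgals3 (-4.83), Cryab (-4.28), the tight junction gene Cldn4 (-4.08), Wnt8a (-4.03) and Upk3a (-3.99) followed.

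Of 17 definitive endoderm genes 11 rose with knockdown in EB with activin, 1 fell and 5 did not pass, as adjusted over the list alone, with Gata4 at 2.43, Cxcr4 at 2.41 and Foxa3 at 2.39 (list adjusted p 5.65e-07). Of 12 extra-embryonic endoderm genes 6 rose and 6 did not pass, with Hnf4a at 4.52 and Apoa1 at 3.00, both also expressed in liver (adjusted over the list alone, 6 rose and 1 fell; list adjusted p 0.000225). Of 14 mesoderm and muscle genes 8 rose, 4 fell and 2 did not pass, with Kdr at least 14.4-fold higher and Myl7 at 3.52 (adjusted over the list alone, 9 and 4; list adjusted p 0.000378). Of 22 bivalent factor genes 12 rose, 1 fell and 9 did not pass, with Tbx2 at 3.21 (adjusted over the list alone, 12 and 2; list adjusted p 1.85e-08), 3 of the 12 being primitive streak genes as well. Of 11 p53 response genes 6 fell and 5 did not pass, with Phlda3 at -2.59, the cell cycle inhibitor gene Cdkn1a at -2.32 and Eda2r at -2.11 (adjusted over the list alone, 8 fell; list adjusted p 2.67e-10). Of 10 epiblast genes 4 fell, 1 rose and 5 did not pass, as adjusted over the list alone, with Pou3f1 at -2.77 and Otx2 at 1.23 (list adjusted p 0.0114). Of the 14 primitive streak genes 4 rose, 2 fell and 8 did not pass, with Lhx1 at 2.05 and the streak factor gene T at -3.02 (adjusted over the list alone, 4 and 3; list adjusted p 0.0751, and 0.0353 without shHEB replicate 2). The median of that list was -0.09 while its test pointed up. Under an estimated correlation the list adjusted p was 0.0266 for p53 response and 0.0404 for both extra-embryonic endoderm and epiblast. It was 0.0135 for definitive endoderm and for mesoderm and muscle.

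For the remaining lists of that comparison, 3 of 7 trophoblast genes rose and 4 did not pass, as adjusted over the list alone, with Ascl2 at 2.25 (list adjusted p 0.0114, and adjusted p = 0.0905 with an estimated correlation). Of 4 blood and endothelium genes 2 rose and 2 did not pass, as adjusted over the list alone, Kdr and Runx1 (list adjusted p 0.0295, and adjusted p = 0.0791 with an estimated correlation). Its call ended whichever library was left out, with adjusted p 0.0743, 0.0511 and 0.105 without shControl replicates 1 to 3 and 0.101, 0.108 and 0.0759 without shHEB replicates 1 to 3. Of 17 pluripotency genes 6 fell, 2 rose and 9 did not pass, with Tbx3 at 3.59 (adjusted over the list alone, 8 and 2; list adjusted p 0.0877). In all, 1984 genes changed, 1040 up and 944 down, of which 662 and 619 by at least 2-fold.

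Whether the same genes responded in the 3 states was tested by overlap. Knockdown in EB without and with activin raised 248 genes in common where 63.2 were expected (Fisher exact p 2.58e-89) and lowered 216 where 49.4 were expected (p 1.33e-86), Mesp1 among the first and Cryab among the second. A further 76 genes that rose without activin fell with it, Wnt8a among them, and 87 that fell without it rose with it. Of the 20 genes lowered in ESC, 8 were lowered in EB without activin (1.05 expected, Fisher exact p 3.87e-06) and 8 in EB with activin (1.47 expected, p 4.79e-05), Slc38a10 in both. Of the 15 raised in ESC, 4 were raised in EB without activin (0.911 expected, exact p 0.0108, adjusted 0.013) and 3 with activin (1.22 expected, exact p 0.117), while 6 and 7 were lowered. With replicate number as a block 11 of 36 were raised with activin (3.31 expected, exact p 0.000262), which passed, and 11 were lowered. Of the 20 lowered in ESC, 0 and 1 were raised in EB without and with activin. Expected numbers were computed for the same direction only, so the opposite calls, the 76 and 87 between both EB states included, were not tested. The overlaps therefore do not show that the genes raised in ESC respond alike in EB. When at least a 2-fold change was required, each of the 4 overlaps with ESC held 1 gene and none passed. Across 5710 genes, which are not independent replicates, Pearson's r of the fold changes was 0.259 between both EB states, 0.077 between ESC and EB without activin and 0.12 between ESC and EB with activin.

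Whether knockdown and activin acted independently was tested as an interaction. For primitive streak genes the knockdown effect was lower with activin than without. Wnt8a was at 22.8 CPM ± 5.31 with knockdown alone, 19.9 ± 9.01 with activin alone and 1.21 ± 0.398 with both (SD, n = 3 each), an interaction of -10.88 (SE 0.69). Mixl1 was at 33.1, 78.8 and 60.8 CPM (interaction -7.47, SE 0.51), and T at 11.7, 8.86 and 1.09 CPM (-8.92, SE 0.89). Foxb1 (-10.53), Nkx1-2 (-7.36) and Upk3a (-7.33) were the other large negative values. For the positive ones, Rax was at 165 CPM in control EB without activin, 0.991 with knockdown alone, 2.09 with activin alone and 19.5 with both (interaction 10.59, SE 0.70). Tnnt1, a troponin gene, was at 272, 28.2, 45.1 and 351 CPM in the same order (6.24, SE 0.35). Lhx5 (7.17), the Wnt receptor gene Fzd5 (6.43), Hkdc1 (6.17) and Tlx2 (6.05) were the others. Interactions of genes with 3 or fewer counts in a group, here Lhx5, Tlx2, Foxb1, Nkx1-2 and Upk3a, depend on the prior count and are no bounds.

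By list, the interaction was negative for 13 of 14 primitive streak genes and 1 did not pass, as adjusted over the list alone (list adjusted p 1.06e-56). For 10 epiblast genes it was negative for 5, positive for 1 and 4 did not pass, with Fgf15 at -3.42 (adjusted over the list alone, 7 and 1; list adjusted p 0.000279). For 12 extra-embryonic endoderm genes it was positive for 6 and 6 did not pass, with Hnf4a at 5.29 and Ttr, which had no count with knockdown alone, at a value that depends on the prior count (adjusted over the list alone, 7; list adjusted p 2.27e-06). For 22 bivalent factor genes it was negative for 8, positive for 3 and 11 did not pass, with Eomes at -4.51, Nkx6-1 at -4.43 and Tbx2 at 3.46 (adjusted over the list alone, 10 and 3; list adjusted p 0.000175), and 6 of the 8 are primitive streak genes as well. In all, 1050 genes had an interaction of knockdown and activin, 523 positive and 527 negative.

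The interaction of knockdown with differentiation asks whether the effect in EB without activin differed from that in ESC. Mesp1 had a knockdown effect higher in EB by 9.84 (SE 0.69), Mixl1 by 7.496, Cdx2 by 6.48, Fgf3 by 6.36, Sp5 by 6.28 and Wnt8a by 5.88. The effect was lower in EB for Fezf2 (-9.44), Rax (-7.32), Acta2 (-6.32, SE 0.56), Cryab (-5.21), Myoz1/Synpo2l (-4.90) and Pax6 (-4.71). Cdx2, Sp5 and Fezf2 had a group with 3 or fewer counts, so their values depend on the prior count and are no bounds. The Cdx2 call ended without ESC shControl replicate 3, at 5.87, and the Fezf2 call without ESC shHEB replicate 2, at -6.30. Of 14 primitive streak genes 8 had a positive interaction and 6 did not pass, with Eomes at 5.28 (adjusted over the list alone, 9; list adjusted p 1.07e-29). Of 22 bivalent factor genes 5 were positive, 1 negative and 16 did not pass (adjusted over the list alone, 7 and 2; list adjusted p 0.00108), and 3 of the 5 are primitive streak genes as well. In all 609 genes had this interaction, 342 positive and 267 negative.

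Activin in shHEB EB was compared in the same way. Of 13 neuroectoderm genes 12 fell and 1 did not pass, with Hes3 lower by a ratio of 13180 (95% counting interval 2366 to 520800) and Pax2 by 804 (222 to 6643) (adjusted over the list alone, 12 fell and 1 rose; list adjusted p 9.62e-18). Of 17 definitive endoderm genes 16 rose and 1 did not pass, with Prdm1 at 4.93 and Gata6 at 4.38 (adjusted over the list alone, 17; list adjusted p 1.08e-29). Of 14 primitive streak genes 7 rose, 4 fell and 3 did not pass, with Gsc at 4.32, Tbx6 at -4.62 and T at -3.42 (adjusted over the list alone, 8 and 4; list adjusted p 0.000381). Of 7 trophoblast genes 4 rose, 1 fell and 2 did not pass, as adjusted over the list alone, with Krt7 at 5.01 and Cdx2 lower by a ratio of 113 (95% counting interval 38.4 to 552) (list adjusted p 9.13e-08). In all 3509 genes changed, 1631 up and 1878 down.

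Genes responsive to activin were taken by the effect averaged over both hairpins. That effect is independent of the interaction only where shControl and shHEB groups have equal spread. Library pairs reached a chi-square per degree of freedom of 28.8 and 34.4 in shHEB EB and of 16.85 and 12.9 in control EB. Its lowest values were 6.17 and 7.53 against 8.09 and 6.01. A larger spread in shHEB would push the medians up for induced and down for repressed genes, so a bias is not excluded. The median interaction of the 1965 induced genes was 0.21, with 38.9% below 0, and 248 were positive and 179 negative (328 and 209 adjusted over the list alone; list p 0.00823). The median of the 2460 repressed genes was -0.21, with 62.3% below 0, and 132 were positive and 191 negative (144 and 235 adjusted over the list alone; list p 0.0239). Genes chosen on control EB alone gave medians of -0.31 and 0.29, the opposite signs, and genes chosen on shHEB EB alone gave 0.62 and -0.53. Both choices share libraries with the interaction. Over genes with more than 3 counts in each group the medians were 0.21 and -0.18. With an estimated correlation the list p of the main choice was 0.0361 for induced and 0.0233 for repressed genes. With median-of-ratios scaling as well it was 0.0909 and 0.0301.

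The authors' deposited table for ESC called 344 genes at an adjusted p under 0.05, the authors' deposited table for EB without activin 2194 and the authors' deposited table for EB with activin 2752. Of the 35, 1448 and 1984 genes called here, 33, 1351 and 1851 were also called in the authors' deposited tables, all in the same direction. Tcf12 and Rpsa were not among the 33 for ESC. There Tcf12 stood at -5.721 without an adjusted p, and Rpsa at -0.997 (DESeq2 adjusted p 0.0647). The authors' tables called Tcf12 in EB without activin, at -1.751 (adjusted p 0.00236), and not with activin, at -1.244 (adjusted p 0.108). Mesp1 stood at 9.69 in the authors' deposited table for EB without activin and Rax at -7.37.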

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

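Counting other splits of the libraries was planned, while all expectations and the tests of the 3 weighed patterns were set after the results were seen, and the splits within culture states were added after the splits into any groups gave shares of 0.05 or more. The results here stand out because the effect of knockdown differed between culture states by a test of the difference itself. For activin, 1050 genes had such an interaction, with Rax at 10.585, Lhx5 at 7.175, Fzd5 at 6.432, Tnnt1 at 6.236, Hkdc1 at 6.171 and Tlx2 at 6.047, and with Wnt8a at -10.883, Foxb1 at -10.528, T at -8.92, Mixl1 at -7.472, Nkx1-2 at -7.356 and Upk3a at -7.332. For differentiation, 609 genes did, with Mesp1 at 9.839, Mixl1 at 7.496, Cdx2 at 6.477, Fgf3 at 6.363, Sp5 at 6.281 and Wnt8a at 5.876, and with Fezf2 at -9.441, Rax at -7.319, Acta2 at -6.318, Cryab at -5.21, Myoz1/Synpo2l at -4.903 and Pax6 at -4.712. The Cdx2 call ended without ESC shControl replicate 3 (5.872) and the Fezf2 call without ESC shHEB replicate 2 (-6.298). Values of genes with 3 or fewer counts in a group depend on the prior count and are no bounds (Lhx5, Tlx2, Foxb1, Nkx1-2 and Upk3a for activin, and Cdx2, Sp5 and Fezf2 for differentiation).

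Lists with an interaction of knockdown and activin were post-implantation epiblast (adjusted p 0.000279), primitive streak (1.06e-56), extra-embryonic endoderm (2.27e-06) and bivalent factors (0.000175). Trophoblast (0.0164), the activin and Nodal pathway (0.00433), BMP targets (0.00361) and p53 response (0.0139) had adjusted p = 0.116, 0.116, 0.0802 and 0.304 with an estimated correlation. Lists with an interaction of knockdown and differentiation were primitive streak (1.07e-29) and bivalent factors (0.00108). The activin and Nodal pathway (0.0266), BMP targets (0.0104), p53 response (1.73e-05) and cholesterol synthesis (0.0377) had adjusted p = 0.268, 0.167, 0.167 and 0.457 with an estimated correlation. The activin and Nodal call ended without ESC shControl replicate 2 (0.103) and ESC shHEB replicate 1 (0.0688). The cholesterol call ended without ESC shControl replicates 1 (0.13) and 3 (0.0563), ESC shHEB replicate 2 (0.265) and EB shControl replicate 3 without activin (0.0586).

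The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05. For knockdown in ESC, 2 of 10 splits gave at least the 35 genes of the real one, the highest other giving 406 (306 higher and 100 lower, Ifitm3 and H19 among them), which points to a structure of the ESC libraries other than the hairpin. For knockdown in EB without activin (1448 genes), in EB with activin (1984), activin in control EB (2598), activin in shHEB EB (3509) and differentiation (6637), 1 of 10 splits gave as many, the real one, and the highest other gave 0. Every other split put libraries of both real groups on each side. Differences between those groups then widen the spread within the sides, so the 0 cannot by itself argue against chance. For the interaction with activin (1050), 5 of 100 drawn splits of 12 libraries into any groups gave as many, the highest other giving 1279, so chance is not excluded by that count. Of the 4 others 3 set groups against each other that followed activin in part (absolute r 0.667, 0.667 and 0.333), and the highest did not (0). With hairpins drawn only within each culture state 1 of 100 did, the real one, the highest other giving 746. Such draws ask whether the hairpin has no effect in either state, which this count argues against. They do not ask whether its effect is equal in both, so chance is not excluded for the interaction. For the interaction with differentiation (609), 7 of 100 splits into any groups gave as many, with 4252 the highest other. The 6 others followed culture state in part (absolute r 0.667 in each). Within states 3 of 100 did, the real one among them, with 977 the highest other. These draws have the same limit as those for activin, so chance is not excluded for this interaction either.

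Primitive streak genes were higher in shHEB than in control EB without activin, 13 of 14. A mixture or exchange with the control EB libraries would keep members between the levels of both control EB groups, but 3 members, Mesp1, Tbx6 and Sp5, had all 3 shHEB libraries above all 6 control EB libraries. A single deviating library is argued against by 12 members called at the fewest when 1 of the 6 libraries was left out. An effect of the hairpin on other targets was not tested and stays open beside an effect of HEB loss, since the labels do not give the number of hairpins.

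Acta2, Myl9, Sidt2/Tagln and Cnn1 were higher in shHEB than in control ESC, Cnn1 with a call that ended whichever ESC library was left out (0.92 to 1.05). The 4 were put together after their values were seen. Of the 14 genes of the mesoderm and muscle list edgeR called only Acta2 over all genes (list adjusted p 0.583), and DESeq2 called 2. The rise is therefore shown for the 4 genes and not for muscle genes in general. Differentiated cells like those of control EB, mixed in, would bring the genes that rise most in EB, which imply a median share of 0.37% of such cells (0.024, 0.445 and 0.767% by library), against 8.41% for Acta2, 41.5% for Myl9, 8.83% for the joint row Sidt2/Tagln and 5.66% for Cnn1. With the split of the ESC libraries that called 406 genes as a term, 4 of the 4 genes were called higher, a test set after another block had been tried. That term kept 34 of the 35 knockdown calls and raised their number to 64, so genes already called could hardly fail it. The test therefore does not decide on a structure of the ESC libraries other than the hairpin. With only the 6 ESC libraries fitted none of the 4 was called by edgeR, though all had an unadjusted p under 0.05. These calls ended with 4 residual degrees of freedom instead of 12 and not with smaller folds, which were 3.08, 1.895, 1.26 and 1.005 (SE 0.40, 0.27, 0.17 and 0.20, adjusted p 0.09, 0.0916, 0.0916 and 0.213), against 3.06, 1.88, 1.24 and 0.99 (SE 0.46, 0.24, 0.17 and 0.19) with all libraries. Fibroblast-like cells were not tested as an explanation and stay open: Thy1, Fn1, Vim and Sparc were at 0.35, 0.37, 0.41 and -0.31 and did not pass.

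For primitive streak genes the knockdown effect was lower with activin than without, in 13 of 14. An exchange of the shHEB EB libraries with and without activin would reverse activin targets, but Lefty1/Lefty2 were higher by 4.123 with activin in shHEB EB. Effects of knockdown and activin that add up on the scale of counts could give negative interactions on the log scale. They predict that the level with both treatments is the sum of the levels with knockdown alone and activin alone minus that with neither. Of the 13 members, 9 had all 3 libraries with both treatments outside the range of such sums over the libraries, which argues against addition for them. Of these, 7 lay below (T, Chrd, Foxa2, Nodal, Tbx6, Mixl1 and Sp5) and 2 above (Lhx1 and Gsc, Gsc at 3505 CPM against a sum of 1871). For the other 4 (Fgf8, Evx1, Eomes and Mesp1) addition and another kind of joint effect cannot be told apart, since their libraries overlap that range.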

How the results depend on the processing

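The settings with only replicates 1 and 3 and with another split of the ESC libraries as a term were chosen after the data were seen; the others were planned. Over 521 results for named genes and 7765 alternative values, 0 of the called ones reversed, 394 lost their call, 40 gained one and 67 that were not called changed sign. The count for knockdown in ESC (35) was 90 with replicate number as a block, 113 with the block within states, 95 without a filter, 1 with only the groups compared, 139 with DESeq2, 23 with replicates 1 and 3 and 64 with the other ESC split as a term; fewer libraries and residual degrees of freedom are part of the setting with only the groups compared, and for the others the cause was not tested. Of the overlaps with the ESC calls, requiring a log2 fold change of at least 1 left 1, 1 and 1 shared genes (ESC and EB without activin, up and down, and ESC and EB with activin, down), with fewer genes called, and the block gave 11 for ESC and EB with activin, up, which then passed. Activin-responsive genes chosen on control EB alone gave medians of -0.313 (induced) and 0.294 (repressed), opposite in sign to the main choice, as that choice shares its libraries with the interaction.

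For lists, the number of the 8 comparisons with a call became, with an estimated correlation, 1 for pluripotency, 3 for epiblast, 0 for blood and endothelium, 2 for trophoblast, 3 for activin and Nodal, 1 for BMP targets, 0 for Hox, 1 for p53 and 0 for cholesterol. With the block it was 5 for E and Id proteins, 6 for neuroectoderm and 1 for epithelial and mesenchymal genes, the last also 1 with median-of-ratios scaling. The cause was not tested.

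Leaving out 1 library gave 10 to 35 genes for knockdown in ESC, 1012 to 1260 in EB without and 1380 to 1805 with activin, 2063 to 2260 for activin in control and 2865 to 3335 in shHEB EB, 6088 to 6371 for differentiation, and 827 to 1023 and 413 to 622 for the interactions with activin and differentiation. The calls of lists ranged over 4 to 6 for activin and Nodal, 5 to 6 for bivalent factors, 0 to 1 for blood, 3 to 4 for BMP, 3 to 4 for cholesterol, 0 to 0 for control genes, 4 to 4 for definitive endoderm, 1 to 4 for E and Id proteins, 0 to 1 for epithelial genes, 3 to 4 for extra-embryonic endoderm, 2 to 4 for Hox, 0 to 0 for hypoxia, 1 to 2 for interferon, 1 to 3 for mesoderm, 3 to 4 for neuroectoderm, 4 to 5 for p53, 3 to 6 for pluripotency, 4 to 5 for epiblast, 0 to 0 for PRC2, 5 to 6 for streak and 4 to 4 for trophoblast. For the other pairs of groups r was not above 0.1 for all 3 replicate numbers, which does not show that they are unpaired. Between control and shHEB ESC r was 0.592, 0.541 and -0.148, so pairing there was not settled. Depth limits genes such as Tcf12, with 1 count over the shHEB ESC libraries.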

Other observations

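The values and tests of this part follow lists fixed before the data were examined. Of 11 p53 response genes 4 fell with knockdown in EB without activin, Trp53inp1 (-2.09) and Phlda3 (-1.21) among them, and 7 did not pass (adjusted over the list alone, 8 fell). The list had adjusted p 8.11e-05, and adjusted p = 0.11 with an estimated correlation. Of 11 cholesterol synthesis genes 4 rose with knockdown in EB without activin and 6 with activin, Mvk (0.73 and 0.65) in both (adjusted over the list alone, 6 and 8). That list had adjusted p 0.000755 and 0.000647, and adjusted p = 0.11 and adjusted p = 0.0905 with an estimated correlation. In control cells 10 of its 11 genes rose from ESC to EB, Nsdhl by 1.66 among them (10 adjusted over the list alone, list adjusted p 0.0183, and adjusted p = 0.331 with an estimated correlation).

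Of 5 Hox genes 4 fell from ESC to EB, Hoxa7 (-3.77) and Hoxb9 (-3.58) among them (4 adjusted over the list alone, list adjusted p 0.0112, and adjusted p = 0.0633 with an estimated correlation). Of 5 interferon response genes 3 rose with activin in control EB, Bst2 (0.78), Cxcl10 (4.88) and Usp18 (3 adjusted over the list alone, list adjusted p 0.00768). Of 22 bivalent factor genes 11 rose and 7 fell with activin in control EB (adjusted over the list alone, 12 and 7, list adjusted p 0.00894), a call that ended without EB shControl replicate 1 without activin (0.053). Of 6 PRC2 component genes 3 fell from ESC to EB, Mtf2 (-1.87), Eed (-1.79) and Phf19 (-1.56), as adjusted over the list alone, with list adjusted p 0.165. For knockdown in ESC, EB without and EB with activin edgeR and DESeq2 called none of them, with 1, 0 and 2 at an unadjusted p under 0.05. Of 12 hypoxia and glycolysis genes 2 rose and 2 fell with knockdown in EB with activin, Slc2a3 (1.93) and Pdk1 (-1.41) among them (2 and 2 adjusted over the list alone, list adjusted p 0.494). Of 10 epithelial and mesenchymal genes 4 rose and 2 fell with knockdown in EB without activin, Snai1 (3.56), Twist1 (2.45), Fn1 (2.38) and Epcam (-1.27) among them (4 and 2 adjusted over the list alone, list adjusted p 0.0521, and 0.0291 without shControl replicate 2 and 0.011 without shHEB replicate 1). Of 7 control genes 1, B2m (-1.50), fell with knockdown in EB with activin (1 adjusted over the list alone, list adjusted p 0.373), a call that ended without shHEB replicate 1 (-1.198).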
